A study of Danio rerio with 4 samples.

How the data were processed

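RNA was measured in 4 libraries of cells from AB-strain zebrafish embryos at 9 hours post fertilization (hpf), during gastrulation. Embryos were mosaic either for β-catCA, a constitutively active form of β-catenin that switches on Wnt signalling in the cells that carry it, or for green fluorescent protein (GFP) alone. The cells without GFP were taken by fluorescence-activated sorting, so the libraries hold the GFP-negative cells of the mosaics, not chosen by distance to the marked ones, with 2 lots from β-catCA mosaics and 2 lots from control GFP mosaics. RNA was extracted with TRIzol and made into CEL-Seq2 libraries, per the labels' protocols. CEL-Seq2 reads the 3′ end of each transcript and tags each molecule with a unique molecular identifier (UMI), so a gene's count does not grow with its length.

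The authors deposited whole-number UMI counts per Ensembl gene, with 1 column per library and no normalization. Bowtie2 2.3.1, HTSeq 0.6.1 and the GRCz10 build are named, per the submitters' processing notes. Their order, the annotation release, the UMI length and the rule that collapsed UMIs are not given in the sources used here. The deposited table held 32266 gene rows and 5 rows that were no genes (no feature, ambiguous, low quality, not aligned, not unique). Those 5 rows stayed out of library sizes and tests; they held 52.4% and 58.1% of all counts in lots 1 and 2 of the β-catCA mosaics and 57.7% and 58.3% in those of the controls. Whether they count UMIs or reads is not given in the sources used here. Counting could split reads between near-identical gene copies or overlapping genes, and such values are uncertain.

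Gene UMIs per library were 65098 and 8403 in lots 1 and 2 of the β-catCA mosaics, and 61304 and 59260 in lots 1 and 2 of the control mosaics. The smallest of the other 3 libraries thus held 7.05 times as many UMIs as β-catCA lot 2. A count of 0 allowed up to 3 UMIs, which is 45.7, 373.4, 48.3 and 49.4 TMM-scaled counts per 1000000 gene UMIs (CPM) in the same order. Intervals and floors cover counting error only. Of 8640 genes with a UMI, 8225 had a symbol in the symbol table used here; symbols in capitals are human-style names that this table gives to the zebrafish gene. No genome sequence or annotation of the build was used here, so no positions, lengths or GC contents are given.

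Genes were tested with edgeR 4.0.16 in R 4.3.3: trimmed-mean (TMM) factors, filterByExpr with its minimum count of 10, and the quasi-likelihood test with robust=TRUE and Benjamini-Hochberg adjustment at a threshold of 0.05. Library sizes were the totals of all gene UMIs. The filter kept 1071 genes, which held 77.6% of the gene UMIs. Log2 fold changes are β-catCA mosaic minus control mosaic, with standard errors (SE) from the fitted test. CPM are TMM-scaled, except in the plot of summed UMIs and its intervals, which use library totals. With 2 libraries against 2, the smallest two-sided exact p is 0.333, so single values carry no rank test and p-values come from edgeR, limma 3.58.1 or DESeq2 1.42.0. The labels do not say that the lots came from separate clutches, so p-values measure only the spread between these samples, which may be technical. The 2 libraries of a group were not copies: their counts differed beyond sampling noise, with chi-square values of 6.74 and 2.27 per degree of freedom in the β-catCA and control pairs.

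The design, the rule for named genes, 33 gene lists and the alternatives were fixed before the data were examined. Of the 33 lists, 31 were written by hand and 2 (ribosomal protein genes, mitochondrially encoded genes) by symbol pattern; 729 of 769 entries matched the table, 169 of them through a human-style symbol. Lists with at least 5 tested members entered limma's camera test with a preset correlation of 0.01, and camera with an estimated correlation and fry were run beside it. Named genes were, always, ctnnb1, ctnnb2, cdh1, axin2 and anxa1a. Further named genes were up to 12 per direction that passed the threshold with both libraries of one group above both of the other, a mean of at least 20 CPM and a symbol. Where a direction had fewer than 5 of these, the genes with the smallest p filled it to 5. For each list described, up to 4 members with the smallest p were named. Some results for genes that this rule names are not reported here. Genes too sparse for the filter were read from the same fit without the filter. A further test was chosen after the list totals had been seen: the UMIs of each list were summed per library and tested by edgeR as rows beside the tested genes.

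The procedure was tested on simulated data with the means and library sizes of this comparison. Over 20 simulations on about 1059 genes with 200 of them changed, the test called 26.1% of genes changed 2-fold and 84.8% of genes changed 4-fold, and 3.32% of calls were false. With no change the test called 0.1 genes on average among 1071. The summed-UMI test called a 2-fold shift of the enveloping layer list in 7 of 20 simulations. These rates apply to the simulated spread only, which was 1 common dispersion of 0.031 fitted to these libraries and used for every gene. The real pairs had chi-square values of 6.74 (β-catCA) and 2.27 (control) per degree of freedom. The β-catCA value includes the most abundant row, which took 6.22% and 19.0% of the gene UMIs in lots 1 and 2. No such value was computed for simulated pairs, so these values do not show whether the real spread was larger. Whether the rates hold where genes differ in spread was not tested. Alternatives were other normalizations and filters, the lot number as a block, other tests, thinned counts, a threshold of 0.10, and leaving out each library. Added after seeing the data were library sizes of the tested genes only, removal of the most abundant gene and a correction for UMI collisions.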

Results

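Cells without GFP were sorted from 9 hpf zebrafish embryos that carried scattered β-catCA cells or scattered control GFP cells, with 2 CEL-Seq2 libraries per group. Totals were 65098 and 8403 gene UMIs in lots 1 and 2 of the β-catCA mosaics, from 6412 and 2204 genes, and 61304 and 59260 gene UMIs in the control lots, from 5950 and 5841 genes. Over the 1071 tested genes, log2 CPM of the control lots had a Pearson r of 0.91 with each other, and β-catCA lot 1 had r of 0.88 and 0.87 with them. β-catCA lot 2, the shallow library, had r between 0.66 and 0.70 with the other 3. These correlations are across genes, which are not independent replicates.

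The comparison asks how GFP-negative cells of mosaics with unfit Wnt activity differ in expression from GFP-negative cells of control GFP mosaics. Folds and log2 changes are fitted by edgeR, which weighs the libraries by depth, so they differ from the ratios of the mean CPM. In the β-catCA mosaics, the connexin gene gjc4b (ENSDARG00000007099), which encodes a gap junction protein, fell 2.85-fold. It stood at 4113 ± 6.85 CPM (SD, n = 2) against 11741 ± 1724 CPM in the controls (SD, n = 2), a log2 change of -1.51 (SE 0.25). gjc4b had 33 UMIs in β-catCA lot 2, where 1 UMI stands for 124.5 CPM, so its small SD does not show close replicates. The chaperone gene HSPA8 (ENSDARG00000068992) fell 2.41-fold, with means of 6667 ± 1073 CPM in the controls and 2376 ± 1600 CPM in the β-catCA mosaics (SD, n = 2 each). Its log2 change of -1.27 was -2.44 without β-catCA lot 1 and -0.94 without β-catCA lot 2. The splicing regulator PTBP1 (ENSDARG00000031907) fell 2.98-fold, to 369.7 ± 5.26 from 1097 ± 224 CPM. PTBP1 had 3 UMIs in β-catCA lot 2, at the floor of that library, so its small SD does not show close replicates. The RNA helicase gene DDX39A (ENSDARG00000015111) fell 2.19-fold, to 1323 ± 286 from 3115 ± 353 CPM. In the other direction, the keratin gene krt8 (ENSDARG00000058358) rose 2.58-fold, from 504.0 ± 84.1 to 1411 ± 292 CPM. The 14-3-3 gene ywhaqb (ENSDARG00000023323) rose from 414.6 ± 74.0 to 1211 ± 224 CPM, a log2 change of 1.43 (SE 0.37), and SART3 (ENSDARG00000008032), a factor in spliceosome recycling, rose 4.10-fold, with means of 114.2 ± 24.8 CPM in the controls and 383.7 ± 191 CPM in the β-catCA mosaics. SART3 rested on 2 UMIs in β-catCA lot 2, and its log2 change of 2.03 was 1.09 without β-catCA lot 1.

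These genes were among the 9 calls of edgeR's quasi-likelihood test, 3 higher and 6 lower, with 112 of 1071 genes at an unadjusted p under 0.05. Adjusted p-values were 1.6e-04 for gjc4b, 0.013 for HSPA8, 0.028 for DDX39A, 0.033 for PTBP1 and 0.038 for krt8, ywhaqb and SART3. All 9 genes had both libraries of one group above both of the other, as did 40.8% of the tested genes, where chance gives 33.3%. The number of calls depended on single libraries and on the method. It was 4 without β-catCA lot 1, 15 without β-catCA lot 2, 2 without control lot 1 and 1 without control lot 2, and 1 by DESeq2 (8640 genes with its own filter), 11 by limma-voom on the 1071 genes, 2 with a filter of at least 10 counts in every library of a group, 2 with counts corrected for UMI collisions (added after seeing the data) and 0 by edgeR without the filter (220 at an unadjusted p under 0.05). gjc4b and HSPA8 were kept without β-catCA lot 1, 8 of the 9 genes (not HSPA8) without β-catCA lot 2, HSPA8 among the 2 calls without control lot 1, and gjc4b without control lot 2. The split of 3 higher and 6 lower became 0 and 1 with upper-quartile factors and 0 and 2 with library totals alone.

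**Figure D1:**
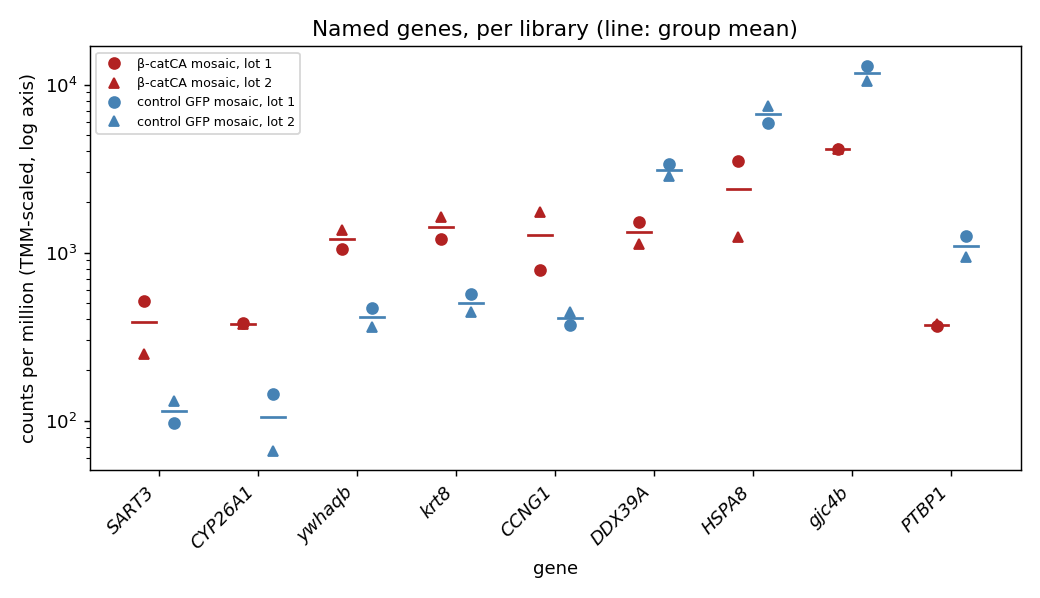
TMM-scaled CPM (log axis) of 5 higher and 4 lower named genes in each of the 4 libraries, with β-catCA mosaics in red, control mosaics in blue, circles for lot 1, triangles for lot 2 and a line at each group mean. gjc4b lies near 4113 CPM in both β-catCA lots and at 12960 and 10522 CPM in the control lots; CYP26A1 and CCNG1 did not pass the threshold.

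The remaining higher genes named by the rule did not pass. CYP26A1 (ENSDARG00000033999), which encodes an enzyme that degrades retinoic acid, was at 377.3 ± 5.52 CPM against 105.4 ± 55.9 CPM (SD, n = 2 each), a log2 change of 1.82 (SE 0.54, edgeR adjusted p = 0.10) that was 2.46 without control lot 1 and 1.37 without control lot 2, and passed in neither case. CYP26A1 had 3 UMIs in β-catCA lot 2, at the floor of that library, so its small SD does not show close replicates. CCNG1 (ENSDARG00000076667), the cyclin G1 gene, was at 1268 ± 672 CPM against 407.4 ± 52.5 CPM, a log2 change of 1.29 (SE 0.40, edgeR adjusted p = 0.12). CCNG1 passed the threshold without β-catCA lot 1, which leaves the shallow lot alone in its group and gave a log2 change of 2.07, and with all libraries thinned to 8403 UMIs. Without β-catCA lot 2 its log2 change was 0.94 and it did not pass (edgeR adjusted p = 0.23).

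Genes of the competition setting itself were mostly too sparse to test. The β-catenin gene CTNNB1 (ENSDARG00000014571) was at 1861 ± 344 CPM in the β-catCA mosaics and 1814 ± 167 CPM in the controls (SD, n = 2 each). Its log2 change was 0.12 with a 95% interval from -0.43 to 0.67 (edgeR adjusted p = 0.94), and its sign turned without the filter, by DESeq2 and without β-catCA lot 1. A 3′ count misses a transgene transcript that ends in another 3′ sequence. Its paralog ctnnb2 had 0 UMIs in all 4 libraries. The Wnt target AXIN2 had 3 UMIs in total. The E-cadherin gene cdh1 had 5 and 2 UMIs in the β-catCA lots and 7 and 9 in the control lots, a log2 change of -0.57 (SE 0.81, edgeR adjusted p = 0.77 without the filter) that turned positive without β-catCA lot 1. Its mean CPM had the other direction, 162.6 in the β-catCA mosaics and 130.5 in the controls. anxa1a, listed as ANXA1 (ENSDARG00000026726), encodes annexin A1, a phospholipid-binding protein known from inflammation control. It had 5 and 4 UMIs in the β-catCA lots and 2 and 2 in the control lots, a log2 change of 1.73 with a 95% interval from -0.17 to 3.63 in edgeR without the filter (unadjusted p = 0.075, adjusted p = 0.77). A difference in anxa1a was not detectable at this depth; the 4 UMIs of β-catCA lot 2 stand for 497.9 CPM, and the log2 change was 1.14 without that lot and 3.19 without β-catCA lot 1.

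Of 33 gene lists, 12 had at least 5 tested members, and by limma's camera 0 of these 12 moved against the other genes, with 0 at an unadjusted p under 0.05. Camera with an estimated correlation also called 0 lists, with 0 at an unadjusted p under 0.05, and fry called 0, with 1 at an unadjusted p under 0.05. Without the filter, camera called 3 of 32 lists: ribosomal protein genes lower (adjusted p = 0.0019), Bmp target and ventral genes lower (adjusted p = 0.011) and enveloping layer genes higher (adjusted p = 0.021). None of the 3 held with an estimated correlation, where the unadjusted p-values were 0.17, 0.065 and 0.24.

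Ribosomal protein genes went both ways: 31 of 56 tested members had negative and 25 positive fitted changes, with a median log2 change of -0.10. Adjusted over the list alone, 5 members were lower and 1 was higher. This adjustment, also given for other lists, covers only the list's own tested members and not the other genes or lists. With few tested members it is close to no adjustment, so it makes no call. RPS6 had a log2 change of -1.10 (SE 0.30), RPL26 of -1.60 (SE 0.44) and RPL6 of -0.99 (SE 0.28), with edgeR adjusted p-values of 0.065, 0.065 and 0.074, so these 3 did not pass. Heat shock and protein folding genes were also divided, with 5 of 11 higher and 6 lower, a median log2 change of -0.15 and a summed change of 0.06 (SE 0.21). HSPB1 held 42.6% of these UMIs, and without it the summed change was -0.35 (edgeR adjusted p = 0.62). HSPA8 fell, and adjusted over the list alone 2 genes were lower. The mitochondrial chaperone gene HSPD1 had a log2 change of -0.76 (SE 0.26), while the small heat shock gene HSPB1 and the Hsp90 gene HSP90AB1 had changes of 0.54 (SE 0.25) and 0.68 (SE 0.32); their edgeR adjusted p-values were 0.20, 0.40 and 0.43.

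Enveloping layer genes, markers of the outer epithelium that covers the embryo, had 13 members with a UMI, and 2 were tested. krt8 rose, also adjusted over the list alone, and its partner keratin krt18a.1 had a log2 change of 0.77 (SE 0.43, edgeR adjusted p = 0.54). The summed UMIs of the list, a test chosen after the totals were seen, were 2.19-fold higher in the β-catCA mosaics: 2382 ± 328 CPM against 1041 ± 191 CPM (SD, n = 2 each; edgeR adjusted p = 0.0060 over 33 lists). krt8 alone held 53.1% of these 290 UMIs. The summed log2 change of 1.13 was 0.83 without krt8 (edgeR adjusted p = 0.26), 1.31 without β-catCA lot 1 (edgeR adjusted p = 0.068) and 0.95 without control lot 2 (edgeR adjusted p = 0.53), so it did not pass there though its direction stayed. Nothing in the labels says that the sort removed this layer.

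**Figure D2:**
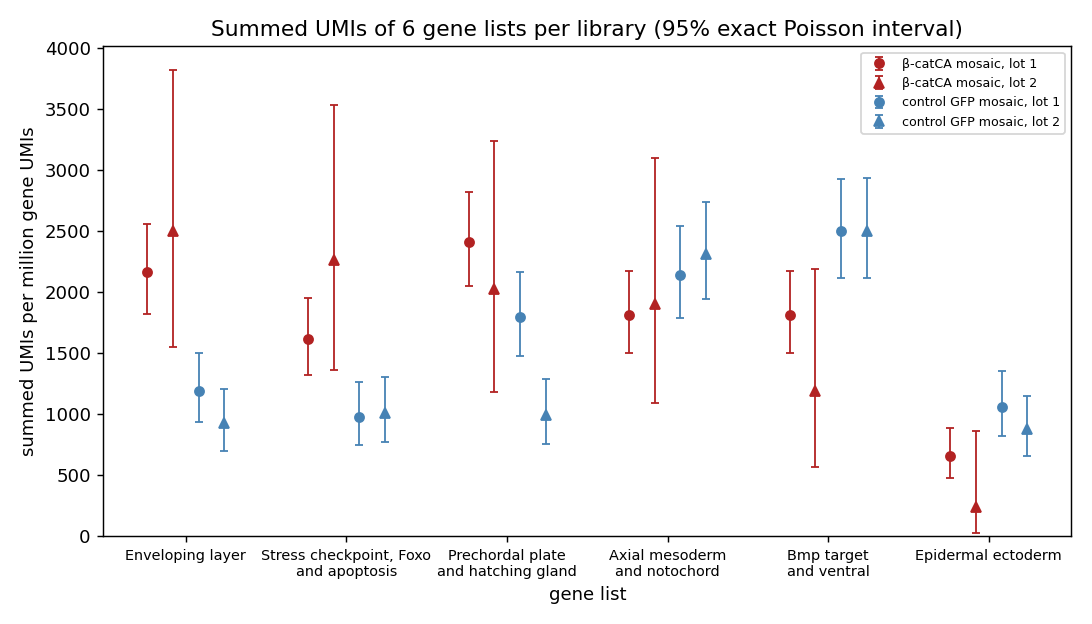
Summed UMIs per 1000000 gene UMIs of 6 gene lists in each of the 4 libraries, with β-catCA mosaics in red, control mosaics in blue, circles for lot 1, triangles for lot 2 and bars for 95% exact Poisson intervals, which cover counting error only. The enveloping layer sums are 2166 and 2499 in the β-catCA lots and 1191 and 928.1 in the control lots; the other 5 lists did not pass the threshold.

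The list of stress checkpoint, Foxo and apoptosis genes had summed UMIs of 1983 ± 540 CPM against 977.0 ± 15.5 CPM (SD, n = 2 each), a log2 change of 0.88 (SE 0.29) that did not pass (edgeR adjusted p = 0.064) but did with DESeq2 size factors (edgeR adjusted p = 0.042). CCNG1 supplied 47.5% of them, and was the 1 of 2 tested members that passed when adjusted over the list alone. Without CCNG1 the summed log2 change was 0.44 (edgeR adjusted p = 0.84). The prechordal plate and hatching gland sum stood at 2255 ± 197 CPM against 1371 ± 565 CPM (edgeR adjusted p = 0.11). Its 3 tested members all had positive changes. These were 1.59 (SE 0.53) for the protease gene ctslb, 1.31 (SE 0.54) for the secreted Wnt antagonist frzb and 0.74 (SE 0.42) for the Wnt receptor gene FZD8. Over all genes 0 passed. Adjusted over the list alone, which covers only 3 tests, ctslb and frzb were higher. They had 2 and 3 UMIs in β-catCA lot 2, no more than the floor of that library. The sum's log2 change of 0.75 was 0.37 without control lot 2 and 1.23 without control lot 1, where it passed (edgeR adjusted p = 0.048).

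Bmp target and ventral genes summed to 1522 ± 392 CPM against 2450 ± 18.6 CPM, a log2 change of -0.56 (SE 0.27, edgeR adjusted p = 0.32) that was -0.99 without β-catCA lot 1 and -0.46 without β-catCA lot 2. Of 6 tested members, 5 had negative fitted changes and 0 passed, over all genes or adjusted over the list alone. For ID3, 1 of the 5, the mean CPM had the other direction, 185.5 in the β-catCA mosaics and 178.9 in the controls. szl, a secreted Bmp feedback inhibitor, had a log2 change of -1.47 (SE 0.61, edgeR adjusted p = 0.39) and TFAP2A, an epidermal and neural crest transcription factor, of -0.54 (SE 0.56). Epidermal ectoderm genes summed to 452.3 ± 288 CPM against 951.4 ± 135 CPM (edgeR adjusted p = 0.32), with 2 UMIs in β-catCA lot 2. Their summed log2 change of -0.70 was -0.55 without β-catCA lot 2 and -1.94 without β-catCA lot 1. The 2 lists share 6 genes, TFAP2A among them, which held 77.2% of the epidermal and 29.1% of the ventral UMIs, so they are not separate evidence.

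Wnt/β-catenin feedback and target genes did not pass. Their summed log2 change was -0.12 with a 95% interval from -0.61 to 0.37. With single libraries left out, it ran from -0.27 (without control lot 1) to 0.01 (without control lot 2). CCND1 held 52.4% of these 628 UMIs, so the sum mostly follows that gene. Without CCND1 the summed change was -0.23 (SE 0.30). All 4 tested members had negative changes, and 0 passed, also adjusted over the list alone. BAMBI, which also stands in the Bmp list, had the largest change, -1.49 (SE 0.81, edgeR adjusted p = 0.53), with mean CPM of 202.0 in the β-catCA mosaics and 204.5 in the controls. SP5, cdx4 and CCND1 had changes of -0.33 (SE 0.49), -0.16 (SE 0.40) and -0.05 (SE 0.28). The mean CPM of SP5 had the other direction, 525.9 in the β-catCA mosaics and 474.8 in the controls. Actomyosin and focal adhesion genes had positive fitted changes in 6 of 6 tested members, with a median log2 change of 0.28 (camera adjusted p = 0.52). The smallest p was that of actb2, with a change of 0.41 (SE 0.24), and CFL1 had a change of 0.64 (SE 0.39). The list's summed change of 0.28 (SE 0.22) was 0.04 without β-catCA lot 1 and 0.40 without β-catCA lot 2. Without actb2, which held 59.1% of the UMIs, it was 0.13. For rhoaa, 1 of the 6, the mean CPM had the other direction, 466 in the β-catCA mosaics and 578 in the controls. Axial mesoderm and notochord genes summed to a log2 change of -0.24 (SE 0.27), with a median of 0.03 over 3 tested members, and tbxta, the notochord and tailbud T-box gene, had a change of -1.07 (SE 0.46, edgeR adjusted p = 0.40), with 0 UMIs in β-catCA lot 2. DNA replication genes and G2 and mitosis genes had summed changes of 0.01 (SE 0.21) and 0.03 (SE 0.23), with medians of -0.25 and 0.07. The sums were -0.11 and -0.22 without β-catCA lot 1, and 0.06 and 0.12 without β-catCA lot 2. No common shift in cell cycle genes was detectable. Of 14 tested DNA replication genes, 5 had positive and 9 negative fitted changes, and 0 passed. fry's mixed test, which asks for changes in either direction, gave that list an unadjusted p of 0.0074. That was the smallest of the 12 lists tested, followed by 0.030 for the heat shock list. It was not adjusted for the number of lists, so it makes no call. The mitochondrially encoded genes had 4 of 10 tested members higher and 6 lower, a summed change of 0.10 (SE 0.22), from -0.11 to 0.29 without single libraries, and a median of -0.25 (camera adjusted p = 0.89). Genes listed as maternal transcripts had a summed change of 0.01 (SE 0.25), which was -0.54 without β-catCA lot 1, and a median of -0.11. YBX1 held 41.2% of these UMIs, and CCNB1 also stands in the G2 and mitosis list. UMI counts do not tell maternal from newly made RNA, so this sum is no measure of developmental age. The other lists also had adjusted p-values above the threshold in the summed-UMI test.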

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

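Tests weighed here were chosen after the results had been seen, except leaving out β-catCA lot 2 for the 9 genes, which was planned. Outside the gene counts, 35.8% of the counts of β-catCA lot 2 were in the row for tags that were not aligned, with a 95% exact binomial interval from 35.2% to 36.5%. That is above both control lots, at 21.1% and 22.9%, and above β-catCA lot 1, at 19.9%; intervals cover counting error only.

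The most abundant row, ENSDARG00000080337, which has no symbol here, took 19.0% of the gene UMIs of β-catCA lot 2 and 6.22%, 6.16% and 5.17% of those of β-catCA lot 1, control lot 1 and control lot 2. Counting error is argued against, since the lower 95% exact binomial bound for β-catCA lot 2 was 18.1%. An excess of the 13 listed mitochondrially encoded genes is also argued against: they were only 1.17 times the mean share of the other 3 libraries. This row has no symbol and stands outside that list. Whether it is itself mitochondrial RNA was not tested, so an excess of such RNA outside the list stays open. A limit on distinct UMIs may account for it. If the UMI had 6 bases, 4096 would exist, and this row's counts of 4046, 3779 and 3066 in the deeper libraries would be close to that limit; corrected for collisions, its shares in the β-catCA libraries came to 22.8% and 22.9%, a ratio of 1.002. The corrected control shares were 15.4% and 9.14%, the correction is steep near the limit, and the UMI length is not given in the sources used here, so this stays a hypothesis.

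For the 9 genes past the threshold, only 3 splits of the 4 libraries into 2 and 2 exist, too few for a share under 0.05; 1 split, the real one, called as many as 9 genes, and the highest of the other splits called 0. That the shallow β-catCA lot 2 made the calls is argued against, since 8 of the 9 genes were still past the threshold without it. A difference between GFP-negative cells of β-catCA mosaics and of control mosaics remains open along with differences between the lots, which the design does not separate from the group with 2 libraries each.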

How the results depend on the processing

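Of these alternatives, 3 kinds were chosen after seeing the data: library sizes of the tested genes, removal of the most abundant gene and the collision correction; so was the whole summed-UMI test. The 9 calls, 3 higher and 6 lower, were 9 again with DESeq2 size factors, library sizes of the tested genes and without the most abundant gene, all 9 of them shared, and 8 with robust=FALSE and 11 by limma-voom. Counts moved to 1 (0 higher, 1 lower) with upper-quartile factors and by DESeq2, and to 2 (0 higher, 2 lower) with library totals only, with at least 10 counts in every library of a group, with the lot number as replicate block and with counts corrected for UMI collisions. They moved to 5 (2 higher, 3 lower) with thinned libraries, where 135 genes were tested, and to 17 (13 lower) at a threshold of 0.10. Without the filter edgeR called 0 (0 higher, 0 lower) of 8640 genes, with 220 at an unadjusted p under 0.05; the 1 call by DESeq2 was among 8640 genes with its own filter, and the 11 by limma-voom were among the 1071 filtered genes. Leaving out single libraries gave 1 to 15 calls (0 to 4 higher, 1 to 11 lower); a lone library was assumed to vary like the other group. The labels do not say whether lots with the same number shared a day or clutch. Their deviations within groups had a correlation of -0.01 across genes. Sampling noise in the shallow β-catCA lot 2 could hide a shared lot effect, so this value does not decide it. The calls kept under the block were gjc4b and HSPA8. gjc4b passed under 15 of 17 alternatives, with log2 changes from -1.74 to -1.39; the exceptions were no filter, at -1.80, and leaving out control lot 1, at -1.38. The log2 change of CTNNB1 turned to -0.15 without the filter and -0.12 by DESeq2, was 0.47 with thinned libraries, and ran from -0.18 to 0.20 without single libraries; that of cdh1 ran from -0.80 to 0.29 without single libraries. Both turned without β-catCA lot 1. Over 13 named genes, 130 alternative values kept their direction and side of the threshold, 67 kept their direction but no longer passed, 2 newly passed and 4 turned. All 67 belonged to genes called in the main test, since a gene that had not passed could not lose a pass. DDX39A kept its pass under 6 of 17 alternatives, PTBP1 and ywhaqb under 6 of 16 and SART3 under 6 of 15. krt8 kept it under 7 of 17 and HSPA8 under 9 of 17. The log2 change of anxa1a ran from 1.14 to 3.19 with adjusted p from 0.596 to 0.995. Lists moved by camera were 0 except without the filter, where 3 moved and 32 instead of 12 could be tested. With an estimated correlation, camera without the filter called 0 of the 32. The summed-UMI test called 1 list, but 2 with DESeq2 size factors, 0 without each list's most abundant member and 0 to 2 when single libraries were left out. Apart from the numbers of genes and libraries tested, the cause was not tested. AXIN2 and ctnnb2, with 3 and 0 UMIs, were given no fold. In β-catCA lot 2, 1 UMI stands for 124.5 CPM.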

Other observations

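The tests of groups and sums in this part were chosen after the values had been seen, and genes named only here likewise. Besides DDX39A and PTBP1, which passed, the RNA helicase gene DDX5 was at 3157 and 2863 CPM in the β-catCA lots against 5184 and 5549 CPM in the control lots, and the U1 snRNP gene SNRPC at 671.0 and 746.9 against 1562 and 1449 CPM; neither passed the threshold (edgeR adjusted p of 0.098 and 0.074). A group of 68 tested splicing and RNA-binding factor genes, picked by symbol pattern after such genes had been seen, had 43 negative changes (63.2%, where all tested genes had 51.8%) and a median log2 change of -0.22. Of these genes, 8 were among the 50 with the smallest p, where its share of the tested genes gives 3.17, and 7 of the 8 were lower. SART3, outside the pattern, was higher. limma's camera gave the whole group an unadjusted p of 0.0055, but the group was picked because of its lead genes. The 60 members outside those 50 had a median log2 change of -0.12 with 36 negative values. Taking out the genes with the smallest p weakens any group, so this split decides nothing and a shift of the group stays open.

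Enveloping layer sums were higher in the β-catCA mosaics, and more cells of this layer in the sorted fraction may be the source. Of its 23 matched genes, 1 (agr1) also stands in the prechordal plate and hatching gland list. The 21 genes other than krt8 and krt18a.1 had 28 and 4 UMIs in the β-catCA lots and 19 and 10 in the control lots, a log2 change of 0.89 with a 95% interval from -0.05 to 1.83, which is too few counts to decide between more such cells and higher keratin expression. That β-catCA lot 2 made the difference is argued against: without it the summed log2 change was 1.03.

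Summed values of ventral and epidermal genes were lower, and those of prechordal plate genes higher, in the β-catCA mosaics. The ventral and epidermal lists share 6 genes, which held 77.2% of the epidermal UMIs, so they are not separate groups. None of these lists passed with all 4 libraries and the filter; Bmp target and ventral genes passed by camera without the filter (not with an estimated correlation), and the prechordal sum passed without control lot 1. A shift of identity from ventral and epidermal to axial could give such values. It is argued against as a general axial shift only weakly. The summed axial mesoderm and notochord genes had a log2 change of -0.24 with a 95% interval from -0.77 to 0.30. Their 3 tested members were uneven: tbxta, also a tailbud gene, had a change of -1.07 with 0 UMIs in β-catCA lot 2. The other tested members, chrd and FOXA2, had changes of 0.17 (SE 0.33) and 0.03 (SE 0.46). A change limited to prechordal plate genes was not tested apart.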
